A study of Rattus norvegicus with 6 samples.

How the data were processed

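RNA was sequenced from 6 samples of H9c2, a myoblast cell line derived from embryonic rat heart. Per the labels, 3 samples are controls and 3 were given ginsenoside Rb2, a saponin of ginseng. The labels' protocol text is the same for all samples and describes Rb2 for 48 h before deprivation of oxygen and glucose for 4 to 6 h and return of both for 12 h. It does not say whether the controls went through the deprivation. Nothing says that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

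The deposited tables hold whole-number counts per gene (24360 rows) and per transcript (44501 rows), with the gene or transcript length. A second pair of deposited tables holds CPM, which equals the deposited count over the column total, scaled to CPM, with no length scaling (largest difference 4.9e-11). HISAT2, DESeq2 and the mouse build mm10 are named in the submitters' processing notes, with no role or order. The known genes carry rat identifiers in all 14622 rows of that type, so which build was aligned to stays unsettled, and no coordinates are given here. Of the other gene rows, 8949 are typed as new gene models, 637 as lncRNA genes outside the annotation and 152 as known lncRNA genes, per the file headers. The new models have identifiers of another form (they begin with ONT), while the labels describe a short-read mRNA kit. Whether reads were long or short is therefore unsettled, which limits what the transcript shares, the slope within genes and the length offset can mean. The tool that built them, the counter and the annotation version are not given in the sources used here. In 99.6% of genes the transcript counts summed to the gene count in all 6 samples. Each table has 18 further per-sample columns that match no sample here, and they were not used.

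Total counts ran from 5193077 (Rb2 replicate 3) to 8793390 (Ctrl replicate 1). A count of 3, the upper limit that a count of 0 allows, was 0.341 CPM in the deepest library and 0.578 CPM in the shallowest. Such limits cover counting error only. No 2 samples were alike within sampling noise: the chi-square per degree of freedom over genes was 1.84 in the closest pair (Rb2 replicates 2 and 3) and 26.6 in the farthest.

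Gene and transcript counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr on group, robust quasi-likelihood fit, 1 term for the group). P-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was a call. Fold changes are log2 of Rb2 over Ctrl, with a standard error taken from the fold change and its F statistic. CPM values given per gene are scaled by TMM. Transcript usage, the share of each transcript in its gene, was tested with diffSpliceDGE of edgeR (Simes p per gene) in genes with at least 2 transcripts past the filter. For Fscn1, transcript shares were also compared with an exact two-sided permutation test, which cannot go below 0.1 with 3 samples against 3. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) where at least 5 members were tested.

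Before the data were examined, the design, 29 gene lists and the rule for naming genes were fixed. The lists hold 585 different genes; 544 matched by symbol, 4 by an older symbol from a RefSeq table of assembly GRCr8, and 37 matched no row and were not analysed here. The rule names the title genes. It names the 10 largest called rises and the 10 largest called falls among genes with a symbol, a mean of at least 5 CPM and groups that do not overlap. It names up to 4 called members of each list by p, or the member with the highest CPM where none is called. For transcript usage it names the 6 genes with the smallest p, each by its 2 transcripts with the largest mean share. For transcripts it names 5 in each direction, or the 5 with the smallest p each way where none passes. Any gene outside the rule is said to be chosen after its values were seen. The text leaves out most members named only for lists without a call.

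The alternatives fixed at the same time were other scalings (RLE, upper-quartile, library size), other filters, DESeq2 1.42.0, limma-voom, limma on log2 of the deposited CPM plus 1 or 0.1, stricter thresholds, the replicate number as a block, other usage and list tests, and each sample left out in turn. Added after seeing the data were a length offset per library (a loess with a span of 0.5 of each library's log-ratio on log2 length), that offset with Ctrl replicate 1 left out, known genes only, and limma-voom with sample quality weights. A check of the fits on simulated counts recovered 47% of 100 genes changed 2-fold and 89% of 100 changed 4-fold among 11551 genes, with 12 unchanged genes called. Among 16679 transcripts it recovered 13% and 54%, with 7 unchanged called. Where the second transcript of a gene was raised, diffSpliceDGE recovered 1% of 100 genes at 2-fold and 11% of 100 at 4-fold among 3099 genes, with 5 unchanged genes called, and limma's diffSplice recovered 5% and 48%, with 11 unchanged called. All 5 simulated lists moved 1.5-fold were recovered. Their members were drawn independently and all moved up, so this check does not cover lists whose members are correlated or go both ways. With a simulated length trend and no change, 38 of 11551 genes were called without the length offset and 2 with it. Fold change and length had an absolute Spearman's rho of 0.71 in that simulation, against 0.264 in the data. The 38 calls are thus no estimate for these data.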

Results

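The series concerns injury of heart muscle cells after loss and return of oxygen and glucose, and its title names acetylation of the splicing factor Sf3a2, the enzymes p300 and Sirt7, and alternative splicing of Fscn1. RNA was measured in 3 control (Ctrl) and 3 ginsenoside Rb2 (Rb2) samples of the rat line H9c2. Total counts were 8793390, 5881914 and 5787587 in Ctrl replicates 1 to 3 and 5521376, 5570308 and 5193077 in Rb2 replicates 1 to 3. Between 19985 and 21150 gene rows had a count. The single comparison in these files is Rb2 against Ctrl, asked of genes, of transcripts, and of the share each transcript takes within its gene. The first principal component of log2 CPM held 42.3% of the variance and ran from Ctrl replicate 1 at -47.0 through Ctrl replicate 2 at -18.1 and Ctrl replicate 3 at 0.56 to the Rb2 samples at 18.1, 23.9 and 22.7.

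Of 11551 genes tested, 219 were higher and 93 were lower in Rb2. Among called genes with a symbol and a mean of at least 5 CPM, the largest fall was in Slc2a1, the glucose transporter GLUT1, from 14.9 ± 1.51 to 2.98 ± 0.29 CPM (SD, n = 3 each; log2 fold change -2.32, SE 0.21, adjusted p = 0.00269). It was followed by LOC100909595 (log2 fold change -1.79), by Nr1d1, a repressor of the circadian clock (-1.74), by Ankrd37 (-1.73), by Adm, the vasodilator peptide adrenomedullin (-1.64), and by Rusc2 (-1.57). Ier3, an immediate-early gene, went from 98.1 ± 13.4 to 36.5 ± 3.15 CPM (log2 fold change -1.43). Fosl2 and Mafk, which encode leucine-zipper transcription factors, and the hexokinase gene Hk2 completed the 10 largest falls of this set, at -1.16, -1.10 and -1.10. In the same set the largest rise was in Sec63, part of the protein translocation machinery of the endoplasmic reticulum, from 3.84 ± 0.77 to 14.2 ± 6.28 CPM (log2 fold change 1.87, SE 0.36, adjusted p = 0.0369). The other large rises were Ptcd3 (1.63), the spliceosomal helicase gene Dhx15 (1.57), Glt8d1 (1.56), Rcn2 (1.56), Tmem123 (1.43), Paip1 (1.42), Cul3, the scaffold of a ubiquitin ligase (1.41), Phf14 (1.35) and Klhl13 (1.34). Of these, Rcn2 and Paip1 missed the threshold under the length offset (edgeR adjusted p = 0.0539 and 0.0513). All 312 called genes had groups that did not overlap, as had 27.2% of all genes tested, where chance gives 10%. At least 2-fold changes were seen in 84 of the higher and 58 of the lower genes.

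By gene type, 207 of the 219 higher genes were known genes. The 93 lower genes were 44 known genes, 44 new gene models, 3 known lncRNA genes and 2 lncRNA gene models outside the annotation. Known genes called higher had a median length of 3193 bases, against 2584 bases in known genes not called. Known genes called lower had a median of 2091 bases. The other gene models called lower had a median of 289 bases, against 267 bases in other gene models not called, so they were not shorter than their own class. The mean transcript length behind a count was 1191 ± 31.9 bases in Ctrl and 1250 ± 5.76 bases in Rb2 (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible). The 20 most abundant genes took 17.1% ± 0.87 of the counts in Ctrl and 15.4% ± 0.14 in Rb2 (SD, n = 3; exact two-sided permutation p = 0.1). With an offset for length in each library, chosen after seeing the data, 159 genes were higher and 107 lower, and 211 of the 312 calls were shared.

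**Figure D1:**
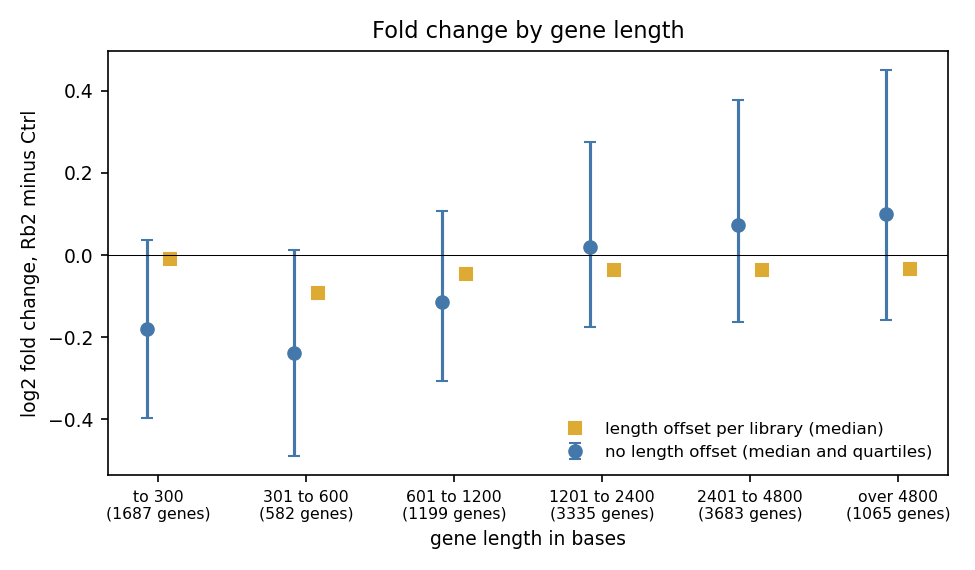
Log2 fold change (Rb2 minus Ctrl) of the 11551 tested genes in 6 bins of gene length, with the number of genes under each bin. Blue circles are medians with bars from the lower to the upper quartile; yellow squares are medians with the length offset per library. The blue medians lie at -0.18 in the shortest bin and 0.10 in the longest.

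The number of called genes changed strongly whichever library was left out, rising without Ctrl replicate 1 or 3 and falling without any other. Without Ctrl replicates 1, 2 and 3 in turn, 605, 2 and 433 genes were higher and 291, 13 and 211 were lower. Without Rb2 replicates 1, 2 and 3, 25, 0 and 1 were higher and 14, 3 and 10 were lower. All 312 genes kept their direction in every such fit, which groups that do not overlap made nearly certain beforehand. Of the 46 called genes that the fixed rule names, leaving out these 6 libraries in the same order ended 6, 41, 5, 35, 45 and 43 calls; LOC100909595 alone of the 46 kept its call in all 20 alternatives, and Slc2a1 lost its call without Rb2 replicate 2 only (adjusted p = 0.0576). The share of called genes that were higher was 70.2%; it was 59.5% with upper-quartile factors (135 higher, 92 lower), 85.3% with library size only (463 and 80), and 85.5% and 85.9% on the deposited CPM (514 and 87, 480 and 79). Library size alone moved the median log2 fold change of all genes from -0.016 to 0.096.

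The genes of the title were not called at the gene level. Fscn1 (ENSRNOG00000056585), which encodes an actin-bundling protein, was at 138 ± 28.2 CPM in Ctrl and 229 ± 79.4 CPM in Rb2 (SD, n = 3 each; log2 fold change 0.74, SE 0.28, edgeR adjusted p = 0.214). Its Rb2 values were 139, 259 and 290 CPM, the first of them within the Ctrl range of 120 to 170 CPM. With DESeq2 the same gene passed the threshold (log2 fold change 0.75, adjusted p = 0.0412), and over all 20 alternatives its adjusted p ran from 0.0412 to 0.542. Sf3a2 (ENSRNOG00000019349), a subunit of the U2 snRNP, was at 22.9 ± 2.17 and 19.9 ± 0.80 CPM (log2 fold change -0.20, adjusted p = 0.492). Sirt7 (ENSRNOG00000036683), a deacetylase, was at 9.98 ± 1.97 and 9.11 ± 2.34 CPM (log2 fold change -0.12, adjusted p = 0.826). Ep300 was not analysed here. None of the 3 passed when adjusted over the list alone.

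As a list, genes induced by low oxygen were lower in Rb2 at camera's preset correlation. Of 18 hypoxia-inducible genes tested, 5 fell, 1 rose and 12 did not pass; adjusted over the list alone, 11 were lower and 3 higher. Ankrd37 went from 15.4 ± 1.27 to 4.61 ± 1.29 CPM, Adm from 13.7 ± 4.45 to 4.33 ± 0.25 CPM, and Higd1a, which encodes a mitochondrial protein, from 463 ± 42.7 to 332 ± 9.66 CPM (SD, n = 3; log2 fold change -0.48, adjusted p = 0.0364). Bnip3l, a receptor for removal of mitochondria by autophagy, rose from 29.3 ± 1.78 to 45.7 ± 1.18 CPM (log2 fold change 0.64, adjusted p = 0.0365). The list's median log2 fold change was -0.63 (camera adjusted p = 0.00273 over 25 lists). With an estimated correlation, its camera adjusted p = 0.401. The estimate for this list was -0.012, below the preset 0.01, so correlation between its own members is not what raised that value. With an estimated correlation camera takes its degrees of freedom from the samples and not from the genes. With n = 3 per group it can therefore hardly call a list, and its adjusted p-values neither support nor undo a call. The glycolysis and glucose uptake list had 3 members that fell and 17 that did not pass, of 20 tested; adjusted over the list alone, 8 were lower and none higher. Beside Slc2a1, these were Hk2 (log2 fold change -1.10, SE 0.18) and the enolase gene Eno2, from 161 ± 11.5 to 84.8 ± 7.11 CPM (SD, n = 3; log2 fold change -0.92, adjusted p = 0.00628). The list's median was -0.19 (camera adjusted p = 0.00082; adjusted p = 0.466 with an estimated correlation), and without Ctrl replicate 3 its call was lost (adjusted p = 0.0648), with a median on log2 CPM of -0.123 against -0.179 with all samples; without Ctrl replicate 2 it stayed called at -0.111. Both lists stayed lower under the length offset, with medians of -0.73 and -0.29. Their size depended on the scaling: the medians were -0.515 and -0.083 with library size only, and -0.501 and -0.065 on log2 of the deposited CPM plus 1.

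**Figure D2:**
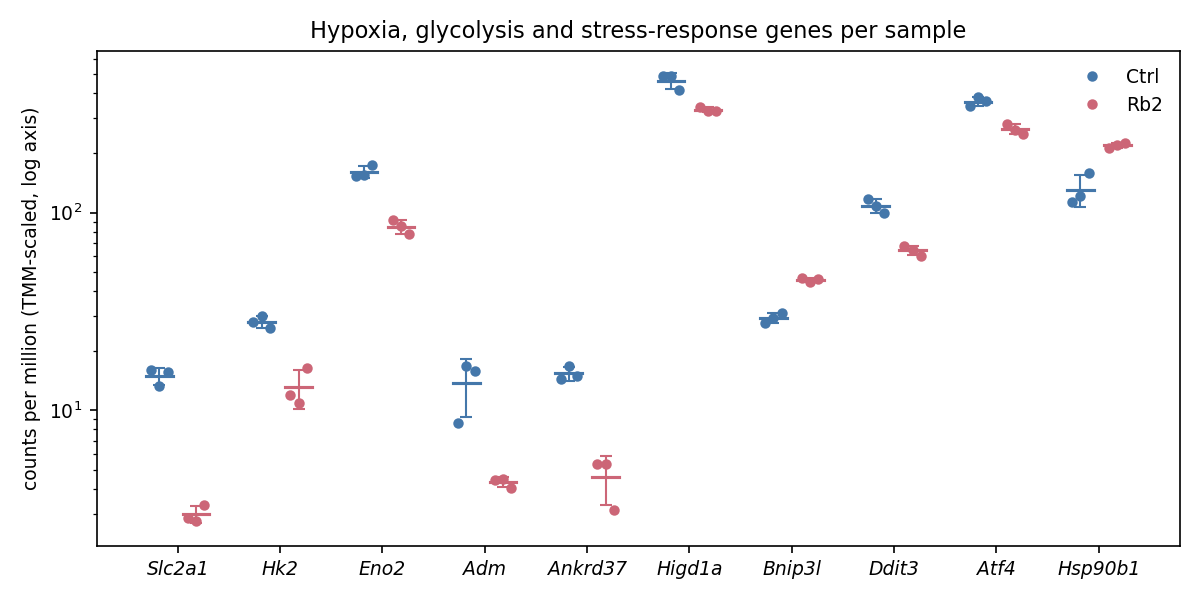
TMM-scaled CPM (log axis) of 10 genes named by the fixed rule, in the 3 Ctrl (blue) and 3 Rb2 (red) samples. Points are samples, horizontal lines means and bars SDs; Slc2a1 lies near 15 CPM in Ctrl and near 3 CPM in Rb2, and Bnip3l and Hsp90b1 are the genes shown that are higher in Rb2.

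Stress-response genes of the endoplasmic reticulum went both ways. Of 20 tested, 4 fell, 2 rose and 14 did not pass, and 5 were lower and 3 higher when adjusted over the list alone. Among those that fell, Atf4, Ddit3 and Ppp1r15a belong to the eIF2 alpha phosphorylation branch. That branch was not tested as a set, and its other members in the list were not counted apart. Atf4, its main transcription factor, went from 364 ± 18.6 to 264 ± 15.1 CPM (SD, n = 3; log2 fold change -0.46, adjusted p = 0.0357), and Ddit3, which encodes CHOP, from 108 ± 8.69 to 64.4 ± 3.59 CPM (-0.75, adjusted p = 0.0192). Ppp1r15a, which encodes GADD34, had a log2 fold change of -0.90 (adjusted p = 0.0318). Hsp90b1, a chaperone of the endoplasmic reticulum lumen, rose from 130 ± 24.3 to 219 ± 5.64 CPM (0.75, adjusted p = 0.0294). The list as a whole was not called (camera adjusted p = 0.71). Of 17 heat shock proteins and co-chaperones, 4 rose and none fell (6 higher and 1 lower adjusted over the list alone). They were Dnaja1 (log2 fold change 0.69), Hspa4 (1.19), Hspd1 (0.52) and Chordc1 (0.68), and that list was not called either (camera adjusted p = 0.136). Chordc1 missed the threshold under the length offset (edgeR adjusted p = 0.0648).

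The lists of SR proteins and hnRNPs and of mitosis were higher in Rb2 at camera's preset correlation. Of 21 SR protein and hnRNP genes, which encode splicing regulators, 4 rose, none fell and 17 did not pass; adjusted over the list alone, 13 were higher and 1 lower. Hnrnpu went from 47.4 ± 11.7 to 90.3 ± 13.1 CPM (SD, n = 3; log2 fold change 0.93, adjusted p = 0.0388). Hnrnpa3 (0.49), Srsf1 (0.64) and Hnrnpa2b1 (0.40) were the other 3, and all 4 missed the threshold under the length offset, at 0.82, 0.40, 0.51 and 0.30. The list's median was 0.47 (camera adjusted p = 3.15e-05). With an estimated correlation, its adjusted p = 0.401. Among 22 genes of the U2 snRNP and 3' splice site recognition, the complex that holds Sf3a2, 4 rose and none fell, with 7 higher and none lower adjusted over the list alone. Sf3b6 went from 147 ± 12.5 to 229 ± 6.66 CPM (log2 fold change 0.63, adjusted p = 0.0194) and Sf3b1 from 13.9 ± 1.70 to 27.6 ± 2.61 CPM (0.99, adjusted p = 0.0261). Dhx15 and Snrpb2 (0.70) were the others. That list was not called (camera adjusted p = 0.334), with a median of -0.03 below 0 and a mean of 0.18 above it. Of 20 mitosis genes, 5 rose, none fell and 15 did not pass, with 8 higher and none lower adjusted over the list alone. Top2a, a topoisomerase of dividing cells, went from 13.5 ± 0.61 to 30.9 ± 1.43 CPM (log2 fold change 1.19, adjusted p = 0.00751). Nusap1 (0.91), Kif23 (0.92) and Bub1 (1.62) also rose, though Bub1 missed the threshold under the length offset (edgeR adjusted p = 0.0635). The list's median was 0.33 (camera adjusted p = 0.000153; adjusted p = 0.401 with an estimated correlation). On log2 CPM its median was 0.369, and leaving out 1 sample gave 0.253 (without Ctrl replicate 2) to 0.588 (without Ctrl replicate 3), with the list called each time. The median gene length was 2840 bases in the SR protein and hnRNP list and 3274 bases in the mitosis list. Over all known genes tested it was 2594.5 bases. Under the length offset the median log2 fold changes of these 2 lists were 0.35 and 0.22, and both were still called (camera adjusted p = 0.000364 and 0.00112).

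The list of ribosomal protein genes was slightly lower in Rb2 at camera's preset correlation. Of 25 tested, 1 fell and 24 did not pass, but 15 were lower and none higher adjusted over the list alone, and 23 had a log2 fold change below 0. Rps3 went from 6516 ± 253 to 5263 ± 161 CPM (SD, n = 3; log2 fold change -0.31, adjusted p = 0.0493). The list's median was -0.26 (camera adjusted p = 0.000265; adjusted p = 0.605 with an estimated correlation). That median was -0.14 with library size only and -0.135 on log2 of the deposited CPM plus 1. Over all genes with a ribosomal protein symbol, the share of counts was 25.8% ± 1.01 in Ctrl and 24.1% ± 0.24 in Rb2 (SD, n = 3; exact two-sided permutation p = 0.1). These genes have many near-identical copies in mammalian genomes, so their counts are uncertain where reads could be split. Of 12 immediate-early genes, Ier3 fell and 11 did not pass, with 2 lower and none higher adjusted over the list alone. The list's median was -0.21 (camera adjusted p = 0.0411; adjusted p = 0.401 with an estimated correlation, which was -0.011 here, below the preset 0.01). With library size only the list's median was -0.101. Its call was lost without Ctrl replicate 3 (adjusted p = 0.185) and without Rb2 replicate 1 (adjusted p = 0.158), with medians on log2 CPM of -0.185 and -0.197. That median was -0.195 with all samples and -0.306 without Rb2 replicate 3, where the list stayed called.

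The other lists held few or no called genes. Hdac2 (log2 fold change 1.06, adjusted p = 0.0465) was the 1 called member of 21 lysine acetyltransferases and deacetylases (camera adjusted p = 0.659), and under the length offset its fold change was 0.96 (adjusted p = 0.0775). Lox, a cross-linker of collagen, rose (0.98) and Cyr61, a secreted matrix protein, fell (-0.69) among 15 matrix genes (camera adjusted p = 0.699). No member was called in the lists of cardiac muscle markers (9 tested, camera adjusted p = 0.836), skeletal muscle markers (9, 0.895), actin regulators (22, 0.481), antioxidant genes (20, 0.481), apoptosis regulators (15, 0.551), p53 targets (12, 0.168), DNA replication (20, 0.205), nuclear-encoded oxidative phosphorylation (28, 0.551), mitochondrially encoded genes (10, 0.481), fatty acid oxidation (17, 0.524), cholesterol synthesis (22, 0.71), autophagy and lysosome (20, 0.71), NF-kB targets (11, 0.71) or interferon-stimulated genes (8, 0.895). Adjusted over the list alone, 4 DNA replication genes and 1 cardiac marker were higher, and 1 antioxidant gene was higher and 3 lower. The p53 targets were called as a list under the length offset (camera adjusted p = 0.0469, lower), but not without it, where the adjusted p with an estimated correlation was 0.466. Markers of other cell types were too few for a list test, with 2 endothelial, 2 epithelial and 1 leukocyte marker past the filter and none called. Fry, which asks whether a list's genes move one way on balance, called 8 of the 25 lists, the 6 above with the heat shock list (adjusted p = 0.0215) and the p53 targets (0.0199). With an estimated correlation camera called none of the 25, with adjusted p = 0.53 for the heat shock list and 0.466 for the p53 targets. That setting can hardly call a list with so few samples.

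**Figure D3:**
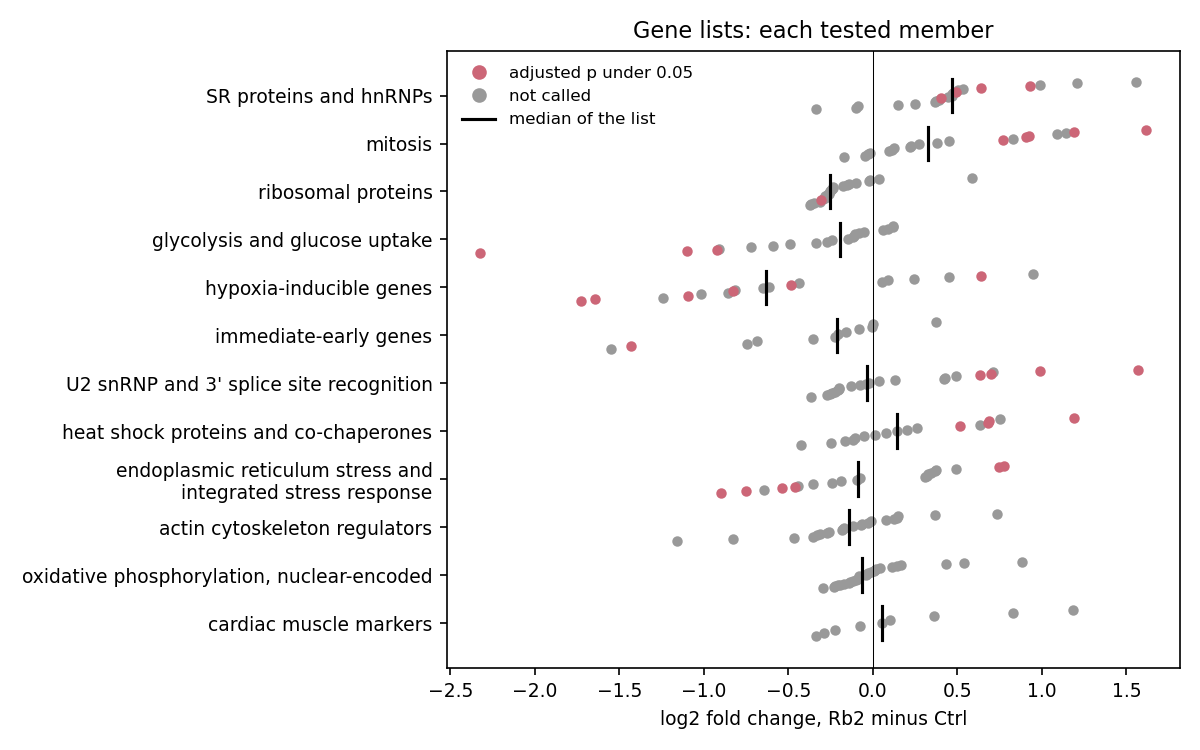
Log2 fold change (Rb2 minus Ctrl, horizontal axis) of each tested member of 12 of the 29 gene lists. Each point is a gene, red where its adjusted p is under 0.05 and grey otherwise, spread vertically by rank; black lines are list medians, which run from -0.63 in the hypoxia-inducible genes to 0.47 in the SR proteins and hnRNPs.

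No transcript was called among 16679 tested with edgeR, while 2304 had an unadjusted p under 0.05. The transcripts with the smallest p did not pass. Among those lower in Rb2 were the annotated transcripts of Slc2a1 (15.1 ± 1.61 to 2.93 ± 0.20 CPM, log2 fold change -2.36), LOC100909595 (-1.89), Ier3 (-1.43) and Eno2 (-0.93) and a new model of Eno1, from 17.2 ± 2.51 to 4.77 ± 0.30 CPM (SD, n = 3; -1.84, adjusted p = 0.0538). Among those higher were a new model of Eif2s2, a subunit of the initiation factor eIF2, from 49.2 ± 3.72 to 102 ± 7.18 CPM (1.05, adjusted p = 0.0538), and a transcript of Top2a (1.17). The other 3 were new models of Szrd1, Tarbp2 and Kif21b with no count in any Ctrl sample. DESeq2 called 307 transcripts, 199 higher and 108 lower. Without Ctrl replicate 1, edgeR called 41.

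Transcript usage was called in 12 of 3361 genes with diffSpliceDGE, and 70 had an unadjusted p under 0.05. Limma's diffSplice called none. In 11 of the 12 genes, a transcript with at least 5 counts in each sample of 1 group had none in the other group. In Kif21b (adjusted p = 0.00349) a new model of 2547 bases held 87.6% ± 2.87 of the gene's counts in Ctrl and none of the 120 counts in Rb2, which allows a share of up to 2.5%. A second model of 2542 bases held 77.7% ± 1.67 in Rb2 and none of the 140 counts in Ctrl, which allows up to 2.14%. In Tarbp2 (adjusted p = 3.48e-07), which encodes a partner of Dicer, the annotated transcript went from 57.7% ± 2.49 to 35.2% ± 3.04 and a new model of 1178 bases from 12.9% ± 3.96 to 16.4% ± 1.69 (SD, n = 3), while a model of 1459 bases had 43, 48 and 44 counts in Rb2 and none of 627 in Ctrl, up to 0.478%. In Szrd1 (adjusted p = 0.000463) the main model held 79.5% ± 3.99 and 82.7% ± 3.01, and a second, of 3206 bases, held 12.4% ± 1.67 in Rb2 and none of 1707 counts in Ctrl, up to 0.176%. A Szrd1 model of 3210 bases differed at least 2-fold the opposite way. An annotated Szrd1 transcript of 3255 bases had 40, 8 and 8 counts in Ctrl and none of 1377 in Rb2, up to 0.218%. In Csnk2b (adjusted p = 0.000666), a subunit of casein kinase 2, the annotated transcript went from 92.1% ± 2.24 to 98.6% ± 0.64, while a model of 941 bases held 6.29% ± 2.17 in Ctrl and none of 2998 counts in Rb2, up to 0.1%. In Rpl31 (adjusted p = 1.24e-06) the main transcripts held 92.6% ± 0.55 and 93.6% ± 0.43, and 5.67% ± 0.19 and 5.87% ± 0.40, while a model of 467 bases had 105, 215 and 224 counts in Ctrl and none of 39901 in Rb2, up to 0.00752%. In Uchl3 (adjusted p = 0.000754) they held 70.7% ± 6.68 and 54.7% ± 14.7, and 29.3% ± 6.68 and 25.2% ± 4.06, while a model of 906 bases had 86, 162 and 41 counts in Rb2 and none of 1192 in Ctrl, up to 0.252%. For these 6 genes limma's adjusted p ran from 0.18 to 0.586. On simulated counts diffSpliceDGE recovered 11% of 4-fold changes in a gene's second transcript, with 5 unchanged genes called of 3099, and limma 48%, with 11 called, so changes of this size can go uncalled by either test.

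Fscn1, the gene whose splicing the title names, showed no detectable difference in transcript usage (3 transcripts tested, diffSpliceDGE of edgeR, adjusted p = 1). Its main model, of 2632 bases, held 83.4% ± 1.81 of Fscn1 counts in Ctrl and 85.5% ± 3.26 in Rb2 (SD, n = 3; exact two-sided permutation p = 0.5). A model of 1227 bases held 14.2% ± 1.68 and 13.3% ± 2.86 (exact permutation p = 0.6), and a model of 1310 bases 2.27% ± 2.39 and 1.23% ± 0.45 (exact permutation p = 0.9), where the Ctrl samples held 5.02%, 0.76% and 1.03%. The smallest p this exact test allows is 0.1. On simulated counts diffSpliceDGE recovered 1% of 2-fold and 11% of 4-fold changes in a gene's second transcript. A change of that size in Fscn1 could therefore go uncalled. The annotated transcript of 1479 bases had at most 1 count in any sample. All tested models of Fscn1 are new models of the deposited tables, so which exons they differ by was not analysed here.

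**Figure D4:**
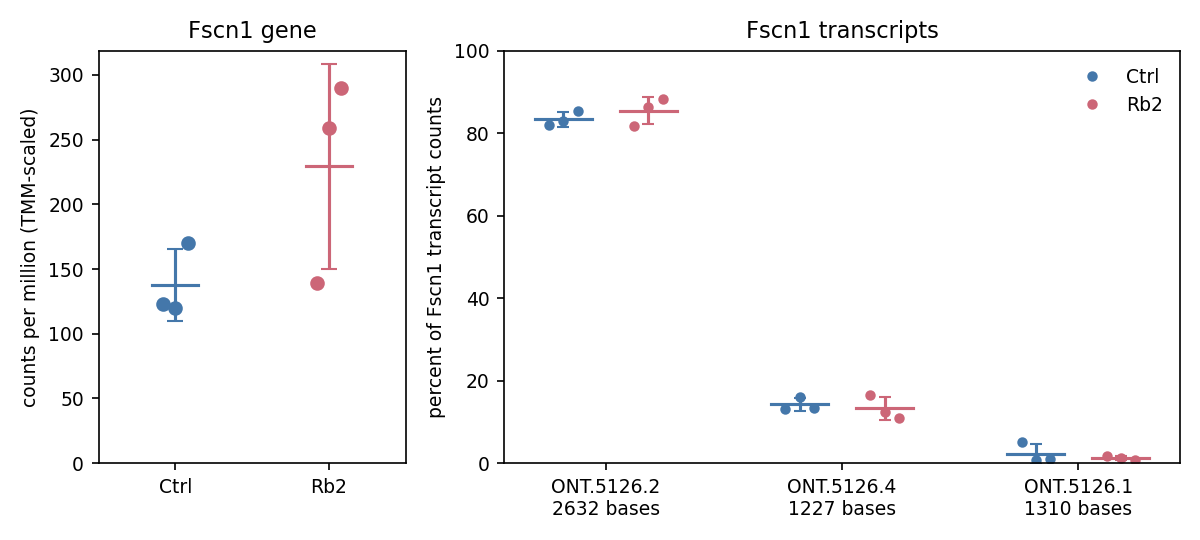
Left, TMM-scaled CPM of Fscn1; right, percent of Fscn1 transcript counts held by each of 3 transcript models, named with their length in bases. Points are the 3 Ctrl (blue) and 3 Rb2 (red) samples, lines means and bars SDs; the main model holds 83.4% in Ctrl and 85.5% in Rb2.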

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

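The length offset, its fit without Ctrl replicate 1, known genes only and sample quality weights were chosen after seeing the data. All 46 called genes that the rule names kept their direction in all 20 alternatives. Their groups did not overlap, so this is little test of them. Their lost calls numbered 1 with RLE factors, 9 with upper-quartile factors, 2 with DESeq2, 7 with limma-voom, 9 with the length offset and 16 with known genes only. The number of genes higher in Rb2 (219) was 135 with upper-quartile factors, 463 with library size only, 386 with no filter, 514 and 480 on log2 of CPM plus 1 and plus 0.1, 84 at 2-fold and 4 at an adjusted p under 0.01. It was 83 with known genes only, 995 with sample quality weights and 512 with the length offset without Ctrl replicate 1. The number lower (93) was 150 with no filter, 58 at 2-fold, 13 at an adjusted p under 0.01, 30 with known genes only, 668 with quality weights and 485 with the length offset without Ctrl replicate 1. Leaving out 1 sample gave 0 to 605 higher and 3 to 291 lower genes. Transcripts called (0) were 27 with no filter, 307 with DESeq2 and 13 with the length offset, and 0 to 41 with a sample left out. Genes called for transcript usage (12) were 19 with at least 1 CPM in 3 samples, 20 with no filter, 0 with limma and 17 to 30 with a sample left out. Gene lists called (6) were 0 with an estimated correlation and 4 to 6 with a sample left out; the adjusted p for Fscn1 usage ran from 0.846 to 1. The log2 fold change of Sirt7, not called in any fit, ran from -0.304 to 0.062 with a sample left out; it was above 0 without Ctrl replicate 3 (0.048) and without Rb2 replicate 3 (0.062). Stricter thresholds lower counts by construction. Camera with an estimated correlation has few degrees of freedom with so few samples. The cause of the other shifts was not tested.

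With the replicate number as a block, 12 genes were higher and 21 lower, 36 of the 46 named calls were lost, 3 genes were called for usage and the 6 lists stayed called. Samples with the same number did not deviate together (correlations of -0.067, -0.061 and -0.007), and no Rb2 sample correlated best with the Ctrl sample of its own number. With 3 samples per group this shows no sign of pairing but cannot exclude it. The labels do not say what the numbers mark.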

Other observations

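The tests of gene families, of the length trend without Ctrl replicate 1 or 2 and in known genes only, of the hypoxia-inducible genes without single libraries, and the comparison of median fold changes before and after the length offset were chosen after the results were seen. Gene families not fixed as lists also held called genes. Of 42 DEAD and DEAH box helicase genes, 5 were higher in Rb2, Dhx15 of the U2 snRNP list and 4 others, among them Ddx1 (log2 fold change 0.70) and Ddx21 (54.2 ± 9.23 to 92.1 ± 4.17 CPM, SD, n = 3; 0.77). Ddx21 missed the threshold under the length offset (edgeR adjusted p = 0.0682). Of 38 translation initiation factor genes, 4 were higher, with Eif2s2 at 1.07 (56.1 ± 4.24 to 118 ± 7.07 CPM, adjusted p = 0.00362), Eif2s3 at 1.19, Eif4g2 at 0.91 and Eif3a at 0.73. Of 23 histone genes, Hist1h1e was lower (-1.75) and 18 had values below 0 or at 0. Camera called these 3 of the 10 families tested (adjusted p = 0.0135, 0.0306 and 0.00581), none with an estimated correlation (adjusted p = 0.566, 0.866 and 0.55) and none under the length offset (0.289, 0.289 and 0.103). Their medians went from 0.094 to -0.026, from 0.049 to -0.039 and from -0.315 to -0.185 under the offset, so the first 2 changed sign. In families that were not called, 2 of 9 septin genes, Sept2 (0.93) and Sept7 (0.88), were also higher. So were 3 of 36 proteasome genes, Psma4 (0.56), Psmc6 (1.13) and Psmd1 (0.65), of which Psmd1 missed the threshold under the length offset (edgeR adjusted p = 0.0543).

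Other splits of the 6 samples into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 312 genes and the highest other split 3, and 1 of the 10 splits gave as many. It called 6 lists against at most 3, again in 1 of 10. For transcript usage it called 12 genes while another split, Ctrl replicates 1 and 2 with Rb2 replicate 1 against the rest, called 18 (and 3 genes), so 2 of 10 gave as many. With edgeR no split called a transcript, so all 10 equal the real one, where 2304 transcripts had an unadjusted p under 0.05 and DESeq2 called 307.

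Across genes the log2 fold change rose with length (Spearman's rho 0.264 over 11551 genes, which are not independent replicates), and rho was 0.317 without Ctrl replicate 1, against that library alone carrying the trend, but 0.169 without Ctrl replicate 2 and 0.113 in known genes only. Under the length offset rho was 0.013, and 61.4% of known genes called higher (127 of 207) and 68.2% of new models called lower (30 of 44) kept their calls; both shares lay between the bounds set beforehand (under 50% for length as the whole cause, over 80% against it) and so decide nothing by those bounds. The comparison of folds, chosen only afterwards, cannot decide it either. These genes were called for large folds in the same data, and a smooth offset moves any such fold little. Medians went from 0.91 (median SE 0.17) to 0.80 (0.16) in the known genes and from -1.45 (0.27) to -1.30 (0.26) in the new models. This shows only that the average trend with length was small beside these folds. The 80 known genes and 14 new models that lost their calls went from 0.90 (SE 0.19) to 0.78 (0.19) and from -1.37 (0.30) to -1.21 (0.28), a small loss that carried median adjusted p-values of 0.0464 and 0.0472 past the threshold, to 0.0595 and 0.0596. A recovery of long transcripts that differs between libraries may account for part, since within genes the slope of transcript level on length was higher in Rb2 by 0.11 log2 units per doubling, but Ctrl and Rb2 samples overlapped (exact permutation p = 0.2), and an effect of the treatment was not separated from it.

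The lower hypoxia-inducible and glycolysis genes are not accounted for by the length trend, since their joint median over 38 genes went from -0.39 to -0.45 under the offset. Leaving out Ctrl replicate 3 brought it to -0.27, the nearest to 0 of the 6 fits without 1 library, so how far that library carries the joint difference stays open. The median of the hypoxia-inducible genes alone stayed at -0.52 or below in all 6 of these fits. Treatment with Rb2 and a control that was handled differently remain untested here.

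Some transcripts had counts in every sample of 1 group and none in the other. With at least 5 counts per sample, 39 transcripts did so (20 present in Ctrl, 19 in Rb2), among them the pair of Kif21b models that differ by a few bases in length. All-or-none assignment of reads between similar models, unrelated to the groups, is a candidate explanation. Another split of the same samples gave 45 such transcripts, more than the real one, while the remaining splits gave 19 to 37. The split with 45 set Ctrl replicates 1 and 2 and Rb2 replicate 1 against the rest, and also called the most genes for usage (18). A difference shared by those samples was not tested. Of the 39, 43.6% (17) had an opposite partner. This is a transcript of the same gene, within 20 bases of length, that differed at least 2-fold the opposite way. The 2-fold rule can miss a partner that holds most of a gene's counts. In Tarbp2, Csnk2b and Uchl3, without a counted partner, annotated transcripts of 1469, 928 and 914 bases changed by -22.45, 6.53 and -16 percentage points. The models of 1459, 941 and 906 bases went the opposite way, though the annotated Uchl3 shares overlapped between groups. In Rpl31 neither main transcript was near 467 bases. How many of the 39 come from such pairs stays open. A switch of isoforms under Rb2 was not tested apart from this, and the 11 usage calls with such a transcript are best checked on reads.

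A hypothesis from the largest falls concerns the circadian clock. Nr1d1 (21.1 ± 3.37 to 6.30 ± 0.38 CPM) and, chosen after their values were seen, Ciart (log2 fold change -1.87) and Bhlhe40 (-1.09; also 1 of the 5 hypoxia-inducible genes that fell) are driven by the same promoter element, the E-box, and all 3 fell in Rb2, which different clock phases in the 2 groups could give. Of the other E-box clock genes, 3 were tested and 66.7% (2) had a log2 fold change below 0 (Per2 -0.79, Tef -0.27, Dbp 0.00). Of 3 genes of the opposite phase, 2 were above 0 (Arntl 0.53, Cry1 0.00) and Nfil3 was at -0.60. None of these 6 was called, and so few genes leave the hypothesis open.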
